A study of Mus musculus with 6 samples.

How the data were processed

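Single-cell RNA sequencing was carried out on testes of adult C57BL6 mice of the genotypes named NONO and NONO deltaER. Per the labels, the testes were digested with enzymes to a cell suspension and libraries were made with the 10x Genomics 3′ chemistry, which tags each captured transcript near its 3′ end with a unique molecular identifier (UMI). The series holds 6 libraries, 3 per genotype. Nothing in the labels says that the libraries of a genotype came from separate animals, so p-values measure the spread between these libraries, which may be technical. What the deltaER alteration removes or changes is not given in the sources used here.

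The deposited matrix holds whole-number UMI counts of 25771 genes in 46495 cells, with no normalization. Per the submitters' processing notes, Cell Ranger 2.1.1 was run against mm10; the annotation version and any step after the counting are not given in the sources used here. The deposited cell table gives for each cell its library (TA to TF), a group named WT or KI, a broad class of 9, a fine class of 17 and a mitochondrial percent. That percent was the deposited one and was used to describe the cells. The group names differ from the genotype labels. WT, the usual short form of wild type, was read as NONO and KI as NONO deltaER, the other genotype of the pair. Were this reading wrong, every direction given here would turn. Libraries TA, TB and TC are then NONO and TD, TE and TF are NONO deltaER. The table does not tie a library to a numbered sample of the labels, so libraries are named by their letters. In the values themselves every cell had at least 500 UMI and at least 201 genes, at most 7995 genes, and at most 5.00% mitochondrial UMI.

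Depth ran from 81042216 to 110018960 UMI per library and from 6261 to 8909 cells. Genes were placed on mm10 with the GENCODE M21 annotation by symbol, and 25127 of 25771 symbols (97.5%) matched 1 gene. Of these, 956 were X-linked and 314 Y-linked.

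Cell classes were taken from the deposited annotation. A set of 140 marker genes, fixed beforehand, was used to describe them, of which 128 were among the measured genes. The class named Differentiated SG carried Stra8, Prdm9 and Dmc1, and the class named Preleptotene SC carried Meiob, Hormad1, Tex101 and Sycp1, all highest there. Stra8 was fixed as a marker of spermatogonia and the others as markers of early spermatocytes, from preleptotene to zygotene. Prdm9 and Dmc1 thus belong to later cells than the name Differentiated SG says. The deposited broad class puts both classes among spermatogonia. The class named Round ST(Step 1-2) lies in the broad class of spermatocytes and had Ccna1 and Aurka, fixed as markers of late spermatocytes, highest. The deposited names are used as labels only. The class named Unknown carried Dcn and Pdgfra and lies in the broad class DCN_enri. Scrublet scored doublets per library but marked only 185 cells (0.398%), which is too few for a caller that has worked. A further alternative therefore left out the 5% of cells with the highest score in each library.

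UMI were summed per library and fine class, since cells are not replicates, and every class with at least 20 cells in at least 2 libraries per genotype was tested. All 17 classes met this. NONO deltaER was compared with NONO by edgeR 4.0.16 (TMM factors, filterByExpr, robust quasi-likelihood fit and test, Benjamini-Hochberg adjustment within each class, threshold 0.05), with R 4.3.3. The same fit was made on the sums over all cells. Log2 fold changes are NONO deltaER over NONO and are followed by their standard error. Levels are CPM, the UMI of a gene scaled to a common total per class and library, as mean ± SD with n = 3 per genotype. The script was tested on simulated counts with 200 changed genes per class. In preleptotene spermatocytes, it recovered 19.4% of 1.5-fold, 65.7% of 2-fold and 89.4% of 4-fold changes (13, 44 and 59 genes), with 12 false calls among 5818 genes. In undifferentiated spermatogonia, it recovered 16.4%, 47.8% and 92.4% (11, 32 and 61 genes), with 14 false calls among 11064 genes. In both simulations false calls made up a larger share of all calls than the threshold of 0.05. Recovery was lower in some classes without calls: in Leydig cells 0%, 4.48% and 69.7% of the same changes (6087 genes), and in Sertoli cells 11.9%, 47.8% and 86.4% (9026 genes).

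Gene lists were tested by camera of limma 3.58.1 on log-CPM with an inter-gene correlation preset to 0.01, for lists with at least 5 measured members, with adjustment over all 428 list and class pairs. The 27 lists were DBHS and paraspeckle, RNA splicing, homologous recombination and double-strand break repair, synaptonemal complex and meiotic cohesin, piRNA pathway, histone-to-protamine exchange, acrosome, sperm flagellum, sperm glycolysis, oxidative phosphorylation, mitochondrially encoded, cytosolic ribosome, heat shock and dissociation stress, endoplasmic reticulum stress, p53 and apoptosis, interferon and cGAS-STING response, circadian clock, steroidogenesis, cholesterol biosynthesis, nuclear hormone receptors and partners, androgen-responsive Sertoli genes, blood-testis barrier and Sertoli adhesion, mitotic cell cycle, spermatogonial stem and progenitor, spermatogenic transcription and RNA regulators, extracellular matrix and fibrosis, and X-linked genes. A preset correlation treats the members as nearly independent. Members of the passing lists did vary together between libraries: the median estimated correlation was 0.145 and 52 of 58 passing pairs lay above the preset, while random lists of 40 genes had class medians of at most 0.00435. The test with an estimated correlation was checked on simulated data, where a shifted list of preleptotene spermatocytes had p = 3.74e-05. The simulated members were drawn independently of each other, so the check does not show its power on lists whose members vary together. In the files the test with an estimated correlation passed 0 of 428 pairs (limma, 13 at an unadjusted p under 0.05, with 21.4 expected by chance). The self-contained test fry passed 0 (23 at an unadjusted p under 0.05).

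Class shares, sex chromosome shares and library quality were compared by exact two-sided permutation tests, which cannot go below p = 0.1 with 3 libraries against 3. In such a comparison 10% of values do not overlap between the genotypes by chance.

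The tests, the gene lists, the markers, the alternatives and the rule for named genes were fixed before the data were examined. The rule names Nono, Sfpq and Pspc1. It adds genes past the threshold whose libraries did not overlap between the genotypes, with a mean of at least 20 CPM in the higher genotype and a symbol that is not a clone or predicted-gene number. Of these it takes the 10 largest changes per direction in the 3 classes with most calls and 3 elsewhere, and the 4 members with the smallest p of each list that passed. Alternatives fixed at the same time were DESeq2 1.42.0, upper-quartile factors, no filter on low counts, only cells with at least 1000 UMI and under 10% mitochondrial UMI, called doublets left out, equal numbers of cells, at least 100 cells per library, an estimated correlation, fry, an edgeR model of cell counts, germ cells as denominator, a clustering of the same cells (Scanpy 1.11.5 with Leiden, resolution 1.0, 25 clusters), another measure of X expression, and each library left out in turn. Fits with the replicate number as a block were planned but not run, since the libraries carry no number.

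After the data were seen, the libraries were found to part into 2 sets by mitochondrial share that cross the genotypes: TA, TB and TF, and TC, TD and TE. The labels name no batch. Added alternatives were this set as a covariate, cells of the highest doublet scores left out, spermatid genes chosen by the levels of 1 genotype, and DESeq2 with another dispersion trend. The last was added because DESeq2 and edgeR differed. In preleptotene spermatocytes 68.7% of genes had a gene-wise dispersion at the floor of DESeq2, which leaves such genes out of its trend. The median trend was 0.0542 in DESeq2 and 0.00901 in edgeR. With floor genes put back at a flat trend of 0.0179, DESeq2 still called 0 genes there. Why the tools differ there was not settled. In a separate simulation of that class, with 200 genes changed 2- or 4-fold and none 1.5-fold, DESeq2 recovered 133 with 3 false calls and edgeR 162 with 13.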

Results

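The transcriptomes of 46495 testicular cells from 6 libraries were compared between NONO and NONO deltaER mice, with 3 libraries per genotype. NONO is a nuclear RNA- and DNA-binding protein of paraspeckles, encoded on the X chromosome. The NONO libraries TA, TB and TC held 8909, 8502 and 7566 cells and 110018960, 92419195 and 85715508 UMI (unique molecular identifiers, 1 per counted transcript). The NONO deltaER libraries TD, TE and TF held 7015, 6261 and 8242 cells and 89870685, 81042216 and 87743022 UMI. Median UMI per cell was 9068 ± 351 in NONO and 8366 ± 462 in NONO deltaER (SD, n = 3 each; exact permutation p = 0.2, adjusted p = 0.333). Median genes per cell was 2873 ± 264 against 2483 ± 158, with no overlap between the genotypes (exact permutation p = 0.1, the smallest that 3 against 3 allows, adjusted p = 0.333). On cells with at least 1000 UMI it was 3001 ± 223 against 2667 ± 211, and TC and TF both had 2826 (SD, n = 3 each; exact permutation p = 0.2). Germ cells made up 91.7% ± 1.00 of the cells in NONO and 91.6% ± 1.05 in NONO deltaER (SD, n = 3 each; exact permutation p = 1).

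Nono itself was measured first. Over all cells its level was 4.96 ± 0.842 CPM in NONO and 5.14 ± 0.158 CPM in NONO deltaER (SD, n = 3 each), a log2 fold change of 0.04 ± 0.14 with an edgeR adjusted p of 0.974. In undifferentiated spermatogonia, where it was highest in NONO, the values were 117 ± 12 and 110 ± 11.5 CPM (log2 fold change -0.13, adjusted p = 0.717). Preleptotene spermatocytes had 34.8 ± 10.2 and 26.9 ± 5.97 CPM (log2 fold change -0.36, adjusted p = 0.768), and Sertoli cells 71.3 ± 11.7 and 73.9 ± 11 CPM (0.03, adjusted p = 0.996). A 3′ tag outside the altered part says nothing on the genotype, so these levels do not check the labels. Its partners of the DBHS family, Sfpq and Pspc1, had log2 fold changes of -0.16 (adjusted p = 0.841) and 0.06 (adjusted p = 0.923) over all cells, and neither passed the threshold in any class where it was tested.

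The share of cells in each deposited class was compared between the genotypes. Undifferentiated spermatogonia, the class with the stem and progenitor cells, were 2.62% ± 0.494 of cells in NONO and 3.92% ± 0.302 in NONO deltaER. The class named differentiated spermatogonia, in which Stra8, Prdm9 and Dmc1 were highest, was 0.979% ± 0.116 against 1.78% ± 0.516. Leptotene to early pachytene spermatocytes were 5.94% ± 0.791 against 4.44% ± 0.0797, round spermatids of steps 4-5 were 17.8% ± 2.70 against 13.6% ± 2.72, and those of steps 5-6 were 10.3% ± 0.613 against 7.79% ± 0.669. The class named round spermatids of steps 1-2 was 4.6% ± 0.285 against 5.14% ± 0.217 (SD, n = 3 each throughout). All 2251 of its cells lie in the deposited broad class of spermatocytes, which goes against that name. Its X-linked share of UMI in NONO was 0.129%, which does not settle the name. That share lay between 0.0372% in late pachytene to early diplotene spermatocytes and 0.543% in step 3. In these 6 of 17 classes the libraries of the genotypes did not overlap, which chance gives in 10% of classes. Each had an exact permutation p of 0.1 and an adjusted p of 0.283. An edgeR model of the cell counts passed 0 classes, with 4 at an unadjusted p under 0.05, a lowest adjusted p of 0.143 and log2 ratios of 0.58 for undifferentiated and 0.86 for differentiated spermatogonia. The libraries also part into sets by mitochondrial share. Without overlap the sign within a set is fixed, so only the size of the difference within each set is of interest. For undifferentiated spermatogonia it was 1.19 percentage points within TA, TB and TF and 1.68 within TC, TD and TE. For differentiated spermatogonia it was 0.143 and 1.23, for leptotene to early pachytene spermatocytes -1.66 and -1.25, and for round spermatids of steps 1-2, 4-5 and 5-6 they were 0.538 and 0.338, -2.69 and -4.06, and -2.97 and -2.15. Classes from a clustering of the same cells gave a difference of -1.43 points in place of -2.47 for steps 5-6 and -0.978 in place of -1.50 for leptotene to early pachytene spermatocytes. For steps 4-5 the difference of -4.24 points became -2.69 without TB and -2.72 without TD.

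**Figure D1:**
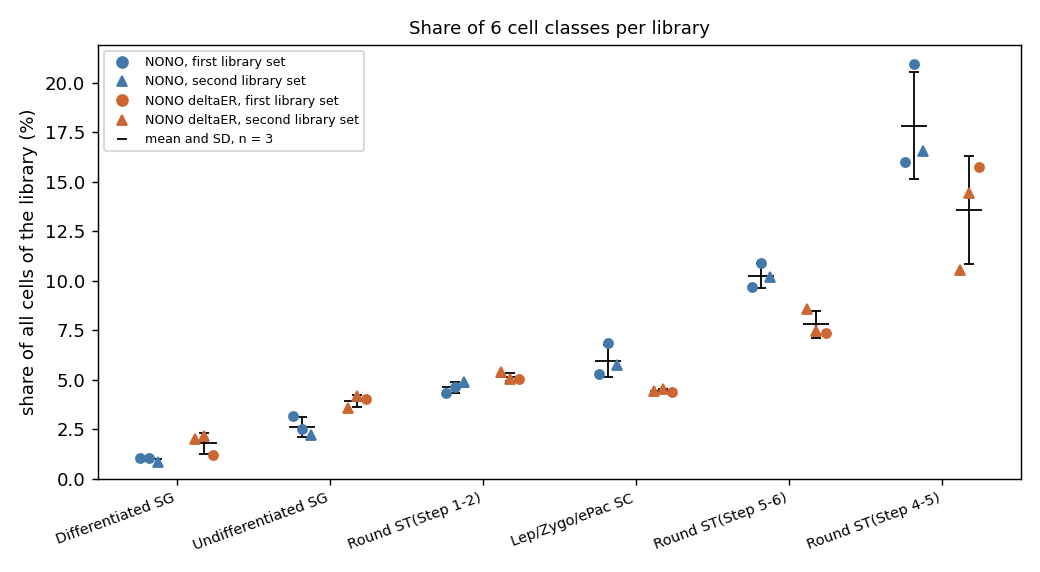
Share of all cells of a library (percent, vertical axis) in the 6 classes whose libraries did not overlap between NONO (blue) and NONO deltaER (orange). Points are libraries, circles the set TA, TB and TF and triangles the set TC, TD and TE, with bars for mean and SD; the means of undifferentiated spermatogonia are 2.62% and 3.92%.

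The class named preleptotene spermatocytes, in which the meiotic prophase genes Meiob, Hormad1 and Sycp1 were highest, had the most genes past the threshold, with 10 higher and 9 lower in NONO deltaER among 5818 tested (edgeR, lowest adjusted p = 0.0104; 683 genes at an unadjusted p under 0.05). Among the genes that rose, Rps6ka5, a kinase that phosphorylates histone H3, went from 118 ± 25 to 220 ± 17.9 CPM (log2 fold change 0.91 ± 0.18, adjusted p = 0.0104), and Foxn2, a forkhead transcription factor, from 71.9 ± 22.8 to 136 ± 14.7 CPM (0.96 ± 0.23, adjusted p = 0.0351). Dip2c rose from 207 ± 34.1 to 351 ± 28.4 CPM (0.77 ± 0.14, adjusted p = 0.0104) and Sdk1, a cell adhesion molecule, from 475 ± 98.0 to 733 ± 76.2 CPM (0.62 ± 0.12, adjusted p = 0.0113). Celf2, an RNA-binding splicing regulator, Gmds, an enzyme of GDP-fucose synthesis, Magi3, a scaffold of cell junctions, Fbxl17, a substrate receptor of an SCF ubiquitin ligase, and the transcription factors Pbx3 and Nfat5 rose by log2 0.81, 0.80, 0.75, 0.65, 0.64 and 0.56. On mm10, Rps6ka5 lies on chromosome 12 at 100548439 to 100726983, Foxn2 on chromosome 17 at 88440711 to 88490533, Dip2c on chromosome 13 at 9276528 to 9668928 and Sdk1 on chromosome 5 at 141241490 to 142215586. The 10 genes that rose span 49.8 to 974 kb, while the 9 that fell span 0.39 to 22.6 kb.

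Among the genes that fell in preleptotene spermatocytes, Hspa2, a germ cell chaperone needed for meiosis, went from 910 ± 76.7 to 645 ± 36.9 CPM (log2 fold change -0.51 ± 0.11, adjusted p = 0.0222), and Hist1h1t, the testis linker histone, from 600 ± 105 to 398 ± 79.5 CPM (-0.61 ± 0.14, adjusted p = 0.0351). Hist1h2aa, a testis histone H2A, fell from 870 ± 175 to 609 ± 78.0 CPM (-0.54 ± 0.13, adjusted p = 0.0470). Its libraries overlap between the genotypes, so it lies outside the rule for named genes and was chosen after its values were seen. Prpf8, the core protein of the U5 spliceosomal particle, Psmd4, a ubiquitin receptor of the proteasome, Eif3i, a subunit of a translation initiation factor, and Anp32b, a histone chaperone, had log2 fold changes of -0.57, -0.71, -0.72 and -0.56. Fam229b had -0.81, and Cdiptos, named for lying opposite Cdipt, had -1.06 (adjusted p = 0.0475). Whether the counting used strand is not given in the sources used here, so Cdiptos may hold UMI of its partner. Hspa2 lies on chromosome 12 at 76404176 to 76406938 and Hist1h1t on chromosome 13 at 23695814 to 23696725. Hspa2 was fixed as a marker of late spermatocytes, and Hist1h1t also had a fold change below 0 in differentiated spermatogonia and Sertoli cells. Whether RNA from later germ cells accounts for the fall of these genes here was not tested. The direction within the library sets is fixed for the 18 genes without overlap and tests nothing there. DESeq2 called 0 genes in this class (184 at an unadjusted p under 0.05, lowest adjusted p = 0.999), as did edgeR without library TE or on cells with at least 1000 UMI. Equal numbers of cells left 3, the library set as covariate 6, and leaving out TC, TD or TF 5, 9 or 12, while leaving out TA gave 108.

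**Figure D2:**
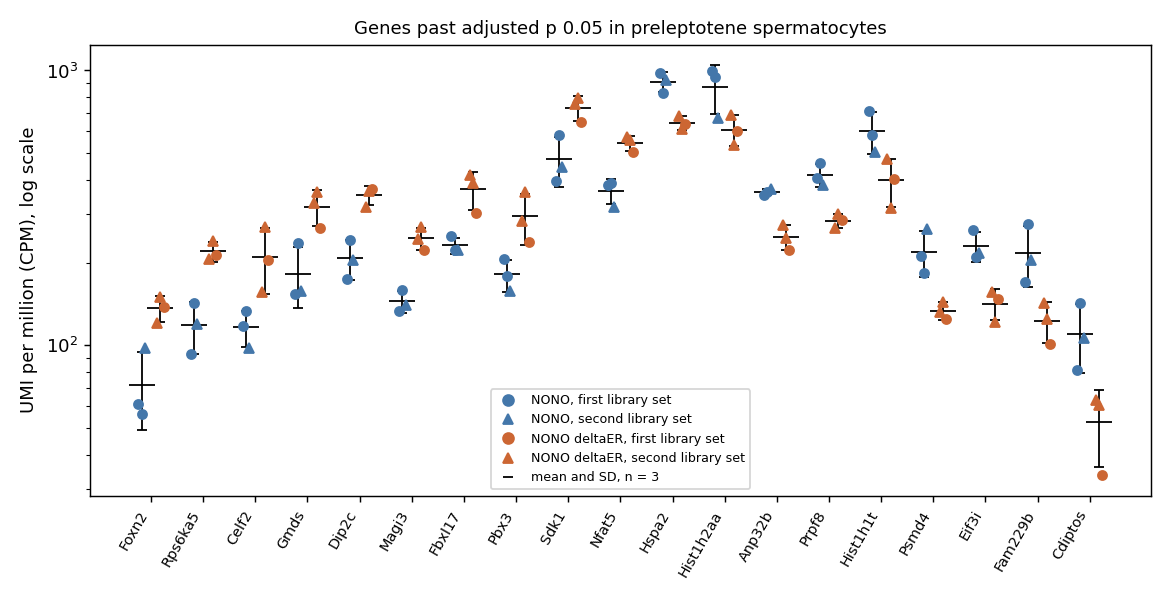
CPM on a log scale (vertical axis) of the 19 genes past the threshold in preleptotene spermatocytes, from Foxn2 to Nfat5 for the 10 higher and from Hspa2 to Cdiptos for the 9 lower in NONO deltaER (orange) than in NONO (blue). Points are libraries, circles the set TA, TB and TF and triangles the set TC, TD and TE, with bars for mean and SD (n = 3); Hspa2 goes from a mean of 910 to 645.

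Lists of genes fixed beforehand were tested with a preset correlation between members (camera) and with an estimated one, and in preleptotene spermatocytes 8 lists passed with the preset only. Of 57 cytosolic ribosome genes, 49 had a fold change below 0 (median -0.21, camera adjusted p = 1.34e-07), with Rps6 at -0.74 and Rpl6 at -0.33. These genes have many processed pseudogenes that could share their reads. Of 140 X-linked genes, 108 were above 0 (median 0.25, adjusted p = 3.88e-06), with Chm at 1.34 and Tsc22d3 at 0.66. Both lists had adjusted p = 0.943 with an estimated correlation and 0 members past the threshold over all genes or adjusted over the list alone. Sperm flagellum genes (21 of 24 below 0, median -0.36, adjusted p = 6.21e-06), with Ropn1l at -0.54, had 1 member past the threshold adjusted over the list alone and 0 over all genes. Oxidative phosphorylation genes (29 of 35 below 0, median -0.30, adjusted p = 0.000119), with Sdhd at -0.72, had 0 by either count. For both, adjusted p = 0.943 with an estimated correlation. In the histone-to-protamine exchange list, 10 of 13 members were below 0 (adjusted p = 0.0120), with Hist1h1t and Hist1h2aa past the threshold over all genes and 3 members adjusted over the list alone. Endoplasmic reticulum stress genes (17 of 21 below 0, adjusted p = 0.0197, Calr at -0.23) and sperm glycolysis genes (13 of 13 below 0, adjusted p = 0.0289, Slc2a3 at -0.68) had 0 members past the threshold by either count. All 3 lists had adjusted p = 0.943 with an estimated correlation. Recombination and double-strand break repair genes were above 0 in 27 of 34 members (adjusted p = 0.0287), with Atm at 0.72 and Brca1 at 0.65 but H2afx at -0.45, and 0 members passed by either count. This list too had adjusted p = 0.943 with an estimated correlation. Across genes, fold change also went with gene span in this class (Spearman correlation 0.354). Whether span accounts for any of these 8 lists was not tested.

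In undifferentiated spermatogonia, 3 of 11064 genes passed the threshold. Fbxl17 rose from 75 ± 1.93 to 148 ± 13.6 CPM (log2 fold change 0.96 ± 0.14, edgeR adjusted p = 0.0470), and it was also among the genes that rose in preleptotene spermatocytes. Fam209, whose product lies in the acrosome of spermatids, fell from 108 ± 17.9 to 45.4 ± 6.50 CPM (-1.25 ± 0.19, adjusted p = 0.0470). Gm5800, a predicted gene outside the rule for named genes and chosen after its values were seen, fell from 60.5 ± 17.4 to 17.3 ± 1.60 CPM (-1.79 ± 0.27, adjusted p = 0.0470). Fbxl17 lies on chromosome 17 at 63057452 to 63500017, Fam209 on chromosome 2 at 172472520 to 172474331 and Gm5800 on chromosome 14 at 51711643 to 51717183. A further count of 121 genes lay at an adjusted p under 0.1, and 1791 at an unadjusted p under 0.05. The number of calls moved widely: DESeq2 called 242, leaving out TA or TF gave 594 or 634, and no filter on low counts gave 825. It was 0 without TB, TC, TD or TE, with the library set as covariate, with equal numbers of cells, on cells with at least 1000 UMI and without called doublets.

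Lists of spermatid genes passed in undifferentiated spermatogonia with the preset correlation only, and 1 gene of them passed over all genes. Of 43 sperm flagellum genes, 41 were below 0 (median log2 fold change -0.68, camera adjusted p = 6.43e-14, but adjusted p = 0.943 with an estimated correlation). Here 20 members passed adjusted over the list alone and 0 over all genes, with Odf3 at -1.17, Drc1 at -1.19 and Cabyr at -1.01. Of 29 acrosome genes, 27 were below 0 (median -0.80, adjusted p = 7.60e-10, but adjusted p = 0.943 with an estimated correlation). Of these, 19 passed adjusted over the list alone and 1 (Fam209) over all genes, with Spaca1 at -1.24, Zp3r at -1.51 and Hyal5 at -1.44. Sperm glycolysis genes were below 0 in 17 of 18 members (median -0.37, adjusted p = 0.000457), with Slc16a7 at -1.09 and 5 members past the threshold adjusted over the list alone and 0 over all genes. Oxidative phosphorylation genes were below 0 in 37 of 50 (adjusted p = 0.0308), with Atp5j at -0.56 and 0 members past the threshold by either count. Both had adjusted p = 0.943 with an estimated correlation. X-linked genes were above 0 in 230 of 355 (median 0.12, adjusted p = 0.0265, but adjusted p = 0.943 with an estimated correlation), with Pola1 at 0.85 and the testis gene Fthl17a at -2.20. There 1 member passed adjusted over the list alone and 0 over all genes. The 73 genes at least 10-fold higher in round spermatids of steps 4-5 than in this class held 0.285% ± 0.0664 of its UMI in NONO and 0.130% ± 0.0392 in NONO deltaER (SD, n = 3 each; exact permutation p = 0.1, adjusted p = 0.4). They were chosen by the mean of both genotypes, which treats the genotypes alike, but from the same libraries that were then compared. A choice by NONO levels alone works against genes that fell. Of the 22 genes chosen in that way, 16 were below 0 (median log2 fold change -0.65). These 22 held 0.0496% ± 0.00804 and 0.0319% ± 0.0123 (exact permutation p = 0.1, n = 3 each). The round spermatid markers fixed beforehand held 0.0885% ± 0.0139 and 0.060% ± 0.0175 (exact permutation p = 0.2, n = 3 each).

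**Figure D3:**
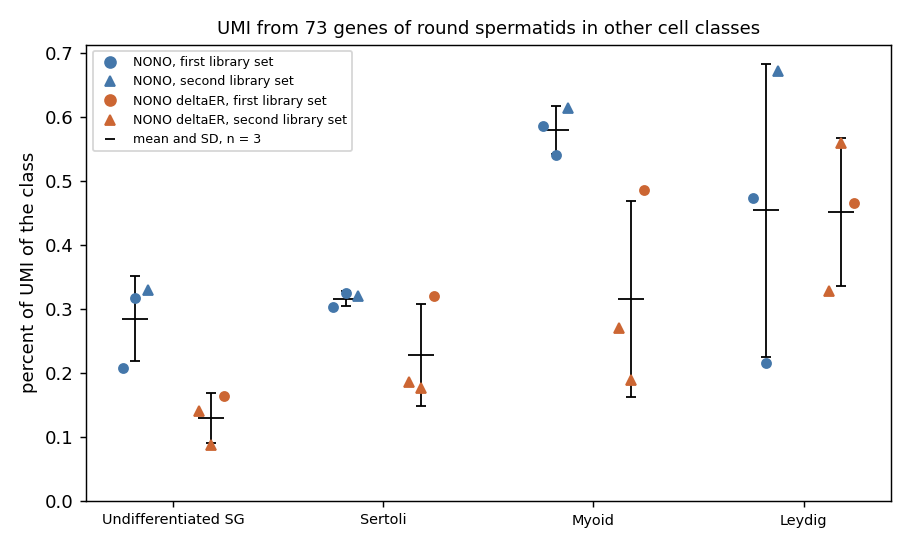
Percent of the UMI of a class (vertical axis) from 73 genes at least 10-fold higher in round spermatids than in undifferentiated spermatogonia by the mean of both genotypes, in NONO (blue) and NONO deltaER (orange). Points are libraries, circles the set TA, TB and TF and triangles the set TC, TD and TE, with bars for mean and SD (n = 3); the means are 0.285% and 0.130% in undifferentiated spermatogonia and 0.454% and 0.452% in Leydig cells.

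In the other 15 classes edgeR called 0 genes. The counts at an unadjusted p under 0.05 were 282 of 4455 tested genes in differentiated spermatogonia, 430 of 12167 in leptotene to early pachytene and 397 of 11623 in late pachytene to early diplotene spermatocytes. In round spermatids they were 280 of 11897 in steps 1-2, 446 of 15151 in step 3, 385 of 15647 in steps 4-5, 392 of 13332 in steps 5-6, 353 of 10911 in steps 6-7 and 145 of 4641 in steps 7-8, and in elongated spermatids 163 of 2747. Somatic classes had 436 of 9026 in Sertoli cells, 202 of 6087 in Leydig cells, 291 of 3705 in myoid cells, 58 of 1270 in macrophages and 101 of 3531 in the class named Unknown. DESeq2 called 6 genes in these 15 classes together, edgeR with no filter on low counts 119, with the library set as covariate 9, and without TC 40. Fold changes of neighbouring germ cell classes were also compared directly, by limma on the log2 ratio of the 2 classes in each library. Over 12 pairs of classes 0 genes differed in their response (lowest adjusted p = 0.201, round spermatids of step 3 against steps 4-5, with 727 genes at an unadjusted p under 0.05). Undifferentiated spermatogonia and preleptotene spermatocytes differed in 0 of 5774 genes (370 at an unadjusted p under 0.05), so the calls of 1 class are not shown to be absent in the other.

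Among the other germ cell classes, differentiated spermatogonia had 13 of 14 histone-to-protamine exchange genes below 0 (median -0.36, camera adjusted p = 0.000306), with Hist1h1t at -0.55, Hist1h2ba at -0.42 and Brdt at -0.47, and 3 members past the threshold adjusted over the list alone against 0 over all genes. Of their heat shock genes 7 of 8 were below 0 (adjusted p = 0.00855), with Hsp90ab1 at -0.41 and 1 member past the threshold adjusted over the list alone and 0 over all genes. Both had adjusted p = 0.943 with an estimated correlation. Leptotene to early pachytene spermatocytes had 60 of 83 X-linked genes below 0 (adjusted p = 0.0114, Vsig1 at -0.62) and 15 of 17 histone-to-protamine exchange genes (adjusted p = 0.0385, Tnp2 at -0.31). In late pachytene to early diplotene spermatocytes 17 of 23 acrosome genes (adjusted p = 0.00779, Spaca1 at -1.17) and 30 of 44 flagellum genes (adjusted p = 0.0124, Cabyr at -0.70) were below 0. All 4 lists had adjusted p = 0.943 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. Round spermatids of steps 4-5 had 20 of 22 endoplasmic reticulum stress genes below 0 (adjusted p = 0.0485, Dnajc3 at -0.12), and those of steps 5-6 had 15 of 20 piRNA pathway genes below 0 (adjusted p = 0.0298, Tdrkh at -0.24). Both had adjusted p = 0.943 with an estimated correlation and 0 members past the threshold by either count.

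The library sets were defined by mitochondrial share, so mitochondrially encoded genes differ between them by construction. Between the genotypes these genes were below 0 in 12 of 12 genes in late pachytene to early diplotene (camera adjusted p = 0.00855) and leptotene to early pachytene spermatocytes (adjusted p = 0.0145). The same held for round spermatids of steps 1-2 (adjusted p = 0.000862) and step 3 (adjusted p = 0.00607), and for 11 of 12 in steps 5-6 (adjusted p = 0.00885). With an estimated correlation, adjusted p = 0.943 for steps 1-2 and adjusted p = 0.956 for the other 4, and 0 members passed over all genes or adjusted over the list alone. In round spermatids of steps 6-7, 9 of 12 were above 0 (adjusted p = 0.0241, but adjusted p = 0.943 with an estimated correlation), with mt-Cytb at 0.57 and 1 member past the threshold adjusted over the list alone and 0 over all genes. The mitochondrial share of UMI was 0.30% and 0.297% in TA and TB and 0.298% in TF, against 0.0862% in TC and 0.130% and 0.103% in TD and TE, so that each genotype holds both levels. With the library set as covariate the direction turned in 4 of these classes, leptotene to early pachytene spermatocytes and round spermatids of steps 1-2, 3 and 5-6, as can follow from the way the sets were made.

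In Sertoli cells, the somatic nurse cells of the tubule, 9 lists were lower and 1 higher in NONO deltaER, again by the preset correlation only. Flagellum genes were below 0 in 38 of 43 members (camera adjusted p = 5.25e-08, Ropn1l at -0.49), acrosome genes in 23 of 29 (adjusted p = 3.88e-06, Fam209 at -0.82), piRNA pathway genes in 15 of 19 (adjusted p = 0.00385, Piwil2 at -0.82), synaptonemal complex genes in 11 of 11 (adjusted p = 0.0441, Sycp1 at -0.38) and mitotic cell cycle genes in 20 of 28 (adjusted p = 0.0135, Hmgb2 at -0.48). For these 5 lists, adjusted p = 0.943 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. Cytosolic ribosome genes were below 0 in 54 of 58 members (adjusted p = 0.000552, Rpl5 at -0.55), mitochondrially encoded genes in 12 of 12 (adjusted p = 0.00373) and oxidative phosphorylation genes in 33 of 41 (adjusted p = 0.0298, Cox7b2 at -0.73). With an estimated correlation, adjusted p = 0.956 for the ribosome and adjusted p = 0.943 for the others, with 0 members past the threshold by either count. Histone-to-protamine exchange genes were below 0 in 11 of 18 (adjusted p = 0.0338), with Hist1h2ba at -1.34, Hist1h1t at -0.82 and 2 members past the threshold adjusted over the list alone. Extracellular matrix genes were above 0 in 8 of 10 (adjusted p = 0.0235), with Nid1 at 0.82 and 2 members past the threshold adjusted over the list alone. Both had adjusted p = 0.943 with an estimated correlation and 0 members past the threshold over all genes. The 73 spermatid genes held 0.316% ± 0.0115 of Sertoli UMI in NONO and 0.228% ± 0.0804 in NONO deltaER (SD, n = 3 each, exact permutation p = 0.3). Of the 64 tested there, 57 were lower (median log2 fold change -0.54). The flagellum, acrosome, piRNA, synaptonemal complex and histone-to-protamine exchange lists hold germ cell genes such as Sycp1 and Piwil2. Whether RNA from germ cells among the Sertoli UMI lowered these lists was not tested.

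Among the other somatic cells, Leydig cells, the source of testosterone, had 10 of 13 histone-to-protamine exchange genes below 0 (median -0.33, camera adjusted p = 5.96e-08), with 5 members past the threshold adjusted over the list alone and 0 over all genes. Protamine and transition protein transcripts of spermatids led them, with Prm1 at -1.74, Prm2 at -1.77 and Tnp2 at -1.45, and the list had adjusted p = 0.943 with an estimated correlation. Markers of elongating spermatids held 2.01% ± 1.01 of Leydig UMI in NONO and 0.80% ± 0.165 in NONO deltaER (SD, n = 3 each; exact permutation p = 0.1). Nuclear hormone receptors and partners were above 0 in 16 of 18 (adjusted p = 0.00230, Nrip1 at 0.74 and Esr1 at 0.68), and mitochondrially encoded genes below 0 in 12 of 12 (adjusted p = 0.000905). Both had adjusted p = 0.943 with an estimated correlation and 0 members past the threshold by either count. Myoid cells had 18 of 19 extracellular matrix genes above 0 (median 0.80, adjusted p = 3.88e-06), with the basement membrane collagens Col4a1 at 1.15 and Col4a2 at 1.25 and 6 members past the threshold adjusted over the list alone. X-linked genes were above 0 in 51 of 63 (adjusted p = 0.000475), with Col4a5 at 1.77 and 1 member past the threshold adjusted over the list alone. Both had adjusted p = 0.943 with an estimated correlation and 0 members past the threshold over all genes. Libraries held 21 to 129 myoid cells, with the fewest in the NONO library TC (34507 UMI). The X-linked share of myoid UMI differed by 0.203 percentage points within TA, TB and TF and by 1.32 within TC, TD and TE. Myoid flagellum (35 of 35 below 0, adjusted p = 2.25e-06, Meig1 at -1.07), acrosome (16 of 17, adjusted p = 0.0298, Fam209 at -1.0) and histone-to-protamine exchange genes (11 of 12, adjusted p = 0.0485, Tnp2 at -1.08) were lower. All 3 had adjusted p = 0.943 with an estimated correlation and 0 members past the threshold by either count. The 73 spermatid genes held 0.580% ± 0.0372 and 0.315% ± 0.153 of myoid UMI (SD, n = 3 each, exact permutation p = 0.1, adjusted p = 0.4). Whether RNA from germ cells lowered these 3 lists was not tested.

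Macrophages had 41 of 42 cytosolic ribosome genes above 0 (median 0.56, camera adjusted p = 1.73e-09) and 9 of 10 mitochondrially encoded genes below 0 (adjusted p = 0.00494), with 0 members past the threshold by either count. Their heat shock and dissociation stress genes were above 0 in 19 of 26 (adjusted p = 0.000715), with Hspa1b at 1.34, Hsph1 at 1.66 and Socs3 at 1.44, and 4 members passed adjusted over the list alone and 0 over all genes. All 3 had adjusted p = 0.943 with an estimated correlation. In the class named Unknown, with fibroblast-like markers, the same stress list was below 0 in 28 of 28 (median -0.62, adjusted p = 2.55e-09, Atf3 at -1.40), RNA splicing genes in 32 of 35 (adjusted p = 4.34e-05, Hnrnpu at -0.78) and DBHS and paraspeckle genes in 17 of 18 (adjusted p = 0.0267, Pspc1 at -0.98). These 3 lists had adjusted p = 0.943 with an estimated correlation, and 0 members passed by either count. Extracellular matrix genes were above 0 in 22 of 22 there (adjusted p = 0.000214, but adjusted p = 0.956 with an estimated correlation), with Col4a1 at 0.73 and 0 members past the threshold by either count. Without TC this list turned (adjusted p = 0.428, against 4.88e-08 to 0.0101 without any other library). Libraries held 23 to 84 macrophages and 34 to 189 cells of the class named Unknown.

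Summed over all cells, 0 of 20958 genes passed edgeR (1257 at an unadjusted p under 0.05), and DESeq2 called 12. Spermatogonial stem and progenitor genes were above 0 in 23 of 31 members (median 0.27, camera adjusted p = 9.06e-06), with Sall4 at 1.17, Stra8 at 0.80 and Foxo1 at 0.59, and 6 passed adjusted over the list alone and 0 over all genes. The list had adjusted p = 0.943 with an estimated correlation, and these sums move with the cell class shares. Mitotic cell cycle genes (34 of 43 above 0, adjusted p = 0.00297, Mki67 at 0.28) and recombination genes (27 of 39 above 0, adjusted p = 0.0298, Prdm9 at 0.62) were higher. Acrosome genes (22 of 29 below 0, adjusted p = 0.000105, Izumo1 at -0.30) and heat shock genes (23 of 29 below 0, adjusted p = 0.00232, Klf2 at -0.34) were lower. For these 4 lists, adjusted p = 0.943 with an estimated correlation and 0 members passed by either count. Flagellum genes were below 0 in 35 of 44 (adjusted p = 0.0240, but adjusted p = 0.946 with an estimated correlation), with Tekt5 at -0.16 and 0 members past the threshold by either count.

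The share of UMI from X-linked genes was compared per class, since Nono is X-linked and the X is silenced in meiosis. It was 1.46% ± 0.0403 in NONO and 1.69% ± 0.0974 in NONO deltaER in preleptotene spermatocytes and 1.96% ± 0.115 against 2.19% ± 0.0873 in undifferentiated spermatogonia. Round spermatids of steps 4-5 had 1.05% ± 0.00672 against 1.06% ± 0.00605 and those of steps 5-6 had 1.47% ± 0.0186 against 1.5% ± 0.00546 (SD, n = 3 each). In these 4 classes the libraries did not overlap (exact permutation p = 0.1, adjusted p = 0.45, with 10% expected by chance), which also fixes the sign within the library sets. By another measure, the mean log2 CPM of X-linked genes against autosomes, only preleptotene spermatocytes of these 4 reached the smallest possible p (difference 0.25, exact permutation p = 0.1). That measure gave p = 0.2 in undifferentiated spermatogonia, 0.3 in steps 4-5 and 0.4 in steps 5-6 (exact permutation). It gave p = 0.1 in elongated spermatids and in round spermatids of steps 6-7 and 7-8, with differences of -0.10, 0.03 and 0.04 (exact permutation). Leptotene to early pachytene spermatocytes, in which the X was nearly silent, had 0.0544% ± 0.00377 against 0.0488% ± 0.00501 (SD, n = 3 each; exact permutation p = 0.3). Y-linked genes did not overlap in preleptotene spermatocytes, with 0.102% ± 0.0120 against 0.137% ± 0.0228 (SD, n = 3 each; exact permutation p = 0.1, adjusted p = 0.9). Over all cells the X share was 0.933% ± 0.0310 against 0.942% ± 0.0230 (exact permutation p = 0.7, n = 3 each).

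In all, 58 of 428 list and class pairs passed with the preset correlation, 14 higher and 44 lower in NONO deltaER, and 0 with an estimated correlation (limma, lowest adjusted p = 0.943). The remaining 8 lists passed in no class. Their lowest adjusted p was 0.0706 for spermatogenic transcription and RNA regulators (round spermatids of steps 5-6), for androgen-responsive Sertoli genes (round spermatids of steps 4-5) and for the blood-testis barrier (all cells). It was 0.103 for interferon and cGAS-STING genes (round spermatids of step 3), 0.140 for the circadian clock (Sertoli cells), 0.154 for p53 and apoptosis (undifferentiated spermatogonia), 0.239 for steroidogenesis (all cells) and 0.446 for cholesterol biosynthesis (differentiated spermatogonia).

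The library sets differed in far more genes than the genotypes. Between TA, TB and TF on one side and TC, TD and TE on the other, edgeR called 3281 genes in round spermatids of steps 4-5, 3017 in step 3, 1664 in steps 5-6, 1654 in steps 1-2, 1597 in leptotene to early pachytene spermatocytes and 3255 over all cells. In undifferentiated spermatogonia it called 2 and in preleptotene spermatocytes 8. The sets were made from the mitochondrial share, so mitochondrial genes follow them by construction. The mitochondrial gene mt-Nd5 and the predicted gene Gm26917 were higher in the first set in 10 classes each, and mt-Co1, mt-Co2, mt-Co3, mt-Nd4 and mt-Nd4l in 8 classes each. Mea1, Gabarap and Csnk2b were higher in the second set in 8 classes each.

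**Figure D4:**
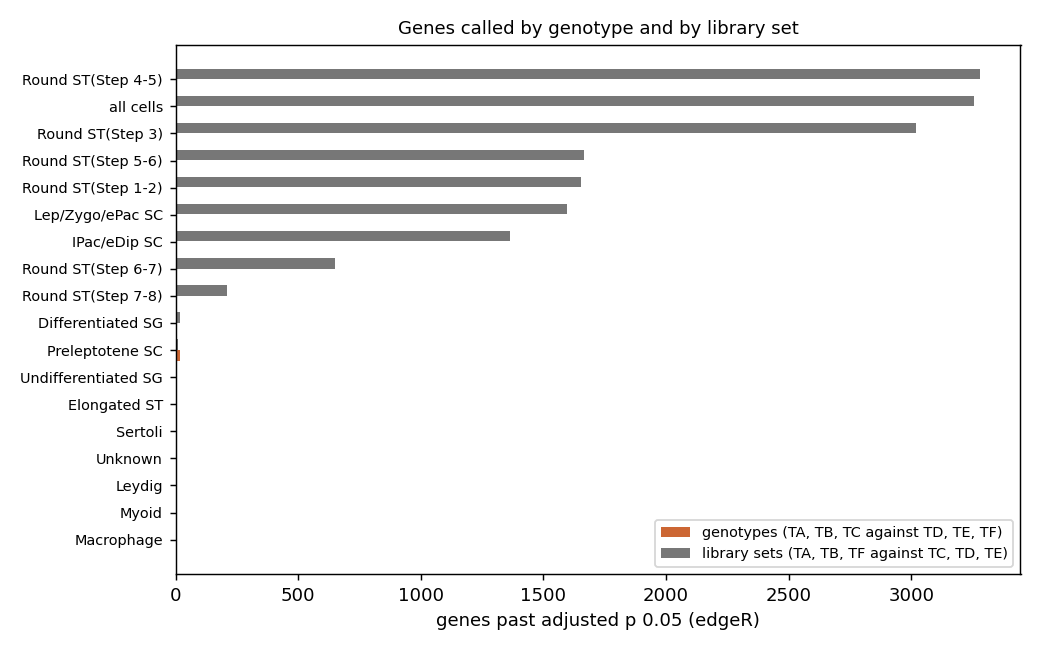
Number of genes past the edgeR threshold (horizontal axis) per cell class, between the genotypes (orange) and between the library sets TA, TB, TF and TC, TD, TE (grey). The bars for the library sets reach 3281 in round spermatids of steps 4-5, while those for the genotypes reach 19 in preleptotene spermatocytes.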

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

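The library set as covariate, the removal of the highest doublet scores and the DESeq2 trend with floor genes were tests chosen after the results were seen. No paired analysis was possible because the libraries carry no replicate number. The planned fits with a replicate block were not run.

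The 19 genes of preleptotene spermatocytes became 0 with DESeq2, 0 with its other trend, 0 on cells with at least 1000 UMI, 3 with equal numbers of cells and 6 with the library set as covariate. Leaving out a library gave 0 (TE), 5 (TC), 9 (TD), 12 (TF), 14 (TB) or 108 (TA). Upper-quartile factors gave 15, no filter on low counts 28 (18 shared), called doublets left out 19 and the highest doublet scores left out 22 (17 shared).

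The 3 genes of undifferentiated spermatogonia became 242 with DESeq2, 315 with its other trend, 825 with no filter on low counts, 38 with upper-quartile factors and 359 without the highest doublet scores. They became 0 on cells with at least 1000 UMI, 0 with equal numbers of cells, 0 with the library set as covariate and 0 without called doublets. Leaving out TB, TC, TD or TE gave 0, TA 594 and TF 634.

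In the other 15 classes together the count of 0 became 6 with DESeq2, 16 with its other trend, 1 with equal numbers of cells, 9 with the library set as covariate, 119 with no filter, 1 without called doublets and 4 without the highest doublet scores. Leaving out a library gave 0 (TD, TE) to 40 (TC), with 1 (TA), 3 (TB) and 12 (TF) between. Over all cells, DESeq2 gave 12, its other trend 22, and leaving out a library 0 to 4 (TF).

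The 58 list and class pairs became 0 with an estimated correlation, 0 with fry and 0 with the library set and an estimated correlation. With the library set alone 59 passed, 40 of them shared in direction. Leaving out a library gave 44 (TA) to 81 (TF). Mitochondrially encoded genes, from which the sets were made, turned with the library set, without and with an estimated correlation: adjusted p = 0.000144 and 0.946 in leptotene to early pachytene spermatocytes, 0.989 and 0.995 in round spermatids of steps 1-2, 0.847 and 0.995 in step 3, and 0.938 and 0.995 in steps 5-6. Extracellular matrix genes in the class named Unknown ranged from an adjusted p of 4.88e-08 (without TB) to 0.428 (without TC, turned).

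With classes from a clustering, which gave no counterpart of differentiated spermatogonia or of steps 1-2, the share difference was -1.43 points against -2.47 for round spermatids of steps 5-6 and -0.978 against -1.50 for leptotene to early pachytene spermatocytes. That of steps 4-5 was -4.24, but -2.69 without TB and -2.72 without TD. Without 1 library, the log2 fold change of Nono ranged from -0.067 (TC) to 0.17 (TA), with none past the threshold. Of the values of the 22 called genes under the alternatives, 137 stayed past the threshold, 170 did not and 0 turned. For other named genes 1034 stayed on their side and 62 passed newly, and for lists 285 stayed, 286 no longer passed and 9 turned. The cause was not tested for any of these changes.

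Depth was lowest in the rarest class: macrophages held 21850 to 135161 UMI per library. Whether depth limited the calls there was not tested. Spermatid genes chosen by NONO levels alone, also added after the results were seen, had a median log2 fold change of -0.65 in undifferentiated spermatogonia, against -1.19 for the 73.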

Other observations

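The tests of the splits, of RNA from other cells, of the library sets (GC content and length apart) and of spermatid transcripts within sets were chosen after the results were seen, as were the 73 spermatid genes, their choice by 1 genotype and the comparison by gene span.

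Gene span went with the fold change in the 3 classes that the deposited broad class puts among spermatogonia. Across genes, which are not independent replicates, the Spearman correlation of fold change and span was 0.331 in undifferentiated spermatogonia, 0.30 in differentiated spermatogonia and 0.354 in preleptotene spermatocytes. Other classes went both ways, with 0.267 in myoid, 0.266 in Sertoli (0.301 in another split, TA, TC and TE) and 0.213 in Leydig cells, 0.0599 in the class named Unknown, -0.149 in macrophages and -0.175 to -0.0697 in round spermatids. Elongated spermatids had 0.149, leptotene to early pachytene spermatocytes 0.0503 and late pachytene to early diplotene spermatocytes -0.0421. In undifferentiated spermatogonia transcript length gave 0.341. In the same order, genes spanning up to 14.2, 17.8 and 15.8 kb had a median log2 fold change of -0.11, -0.10 and -0.14, and those spanning at least 71.3, 75.7 and 68.7 kb had 0.18, 0.11 and 0.14. In preleptotene spermatocytes long genes such as Sdk1, Celf2 and Dip2c were higher, and short ones such as Hspa2 and Hist1h1t lower. Whether span also accounts for the lists that passed in these 3 classes was not tested.

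For that relation, RNA from round spermatids was argued against as the whole cause. Among genes lower in round spermatids the lowest of the 3 correlations was 0.299. These genes were chosen by round spermatids only, so RNA from spermatocytes, elongating spermatids or somatic cells was not tested and stays open. With UMI removed at random down to equal sums per class, the lowest correlation was 0.25. Such removal takes UMI from all genes alike and leaves the expected fold changes as they were. It therefore cannot argue against a difference in the summed UMI, which stays open. Cells per library and UMI per cell were not matched and stay open. Within the library sets the lowest value was 0.0971 (TC, TD and TE, differentiated spermatogonia), so a batch effect stays open, and a difference in intron-containing nuclear RNA by genotype or by preparation may also remain, untested. Of 10 splits, too few for a share under 0.05, only 1 (the real one) reached each correlation, and the highest others were 0.308, 0.217 and 0.242. The 0.308 came from TA, TB and TF against the rest, while the within-set values of that class were 0.283 and 0.168.

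Spermatid transcripts in undifferentiated spermatogonia had a median log2 fold change of -1.19 over the 73 genes, with 69 below 0 and 1 past the threshold. Their choice by the mean of both genotypes treats the genotypes alike, but it used the libraries that were then compared. Chosen by NONO levels alone, which works against genes that fell, 22 genes had a median of -0.65 with 16 below 0. Chosen by NONO deltaER levels alone, which works for genes that fell, 259 had -1.19 with 255 below 0. The most abundant were Sox5 (166 ± 47.3 against 71.8 ± 19.6 CPM), Spaca1 (131 ± 36.2 against 55.3 ± 12.5) and Ankrd7 (131 ± 51.2 against 47.1 ± 17.2; SD, n = 3 each), and 9 of the 73 are in a list fixed beforehand. Without the highest doublet scores the median was -1.29 (-1.10 over the 22 genes). These scores come from the caller that marked too few cells, so they cannot exclude doublets, which stay open. This class had the highest share of called doublets, 2.40%. The medians within the library sets, -0.698 and -1.62, had a sign nearly fixed by the shares, which did not overlap between the genotypes, so the library set stays open. RNA from other cells may explain it and stays open: the highest median in another class was 0.273 (Unknown, 16 genes), where the libraries overlapped. The genes held 0.285% of NONO UMI here, against 0.0366% in differentiated spermatogonia and 0.0509% in preleptotene spermatocytes. Somatic classes held more, from 0.290% (Unknown) to 0.580% (myoid cells). Expression by the spermatogonia themselves, differing by genotype, was not tested.

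The library sets had a median correlation of 0.158 across genes between the responses of 136 pairs of classes, against 0.0985 for the genotypes. A batch of preparation or sequencing may have made them, but the labels name none. An exchange of TC and TF between the genotypes stays open as well. It makes the same split as the sets, so the 3255 genes of that split over all cells give it no separate support. GC content or gene length bias was argued against as the whole cause only, since 15.6% of genes of middling GC content and span were called in round spermatids of steps 4-5, against 21% of all. The set fold change there had a Spearman correlation of -0.376 with span and -0.385 with transcript length, so length may hold a part of it. Which of batch or exchange holds cannot be told apart here, because nothing measured marks the genotype of a library.

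Of the 10 splits of the 6 libraries, which are too few for a share under 0.05, 2 called as many genes as the genotypes in preleptotene spermatocytes (19, highest other 41, TA, TE and TF against the rest) and 2 in undifferentiated spermatogonia (3, highest other 14, TA, TD and TE). For list and class pairs 7 passed as many (58, highest other 76). In each other class and over all cells the genotypes gave 0, which all 10 splits reach. The highest others were 1364 in late pachytene to early diplotene and 1597 in leptotene to early pachytene spermatocytes, 1654, 3017, 3281, 1664, 650 and 209 in round spermatids from steps 1-2 to 7-8, 1 in Sertoli cells and 3255 over all cells, each from TA, TB and TF against the rest, which points to a structure of the samples. With the library set as covariate the genotypes gave 9 genes in the 15 classes together and 0 over all cells. The highest others were 39 in differentiated spermatogonia (TA, TE and TF), 8 in elongated spermatids, and 0 in Leydig cells, macrophages, myoid cells and the class named Unknown.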
